A study of Mus musculus with 6 samples.

How the data were processed

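Methyl-CpG immunoprecipitation followed by sequencing was carried out on the I/11 line, a murine erythroblast line derived from p53-deficient fetal liver at embryonic day 12.5. Per the labels' protocols, cells were infected with lentivirus carrying short hairpin RNA 133 or 14 against Plcg1 or a control hairpin, selected with 1 ug/ml puromycin for 48 h, and harvested 72 h after infection (0 h of differentiation) or after a further 24 h in medium with 10 U/ml erythropoietin (Epo). Per the labels' protocols, 3 ug of genomic DNA was sonicated to about 150 bp, bound to 60 ug of MBD2-Fc, a fusion of a methyl-CpG binding domain to an antibody tail, and the fraction eluted with 1 M NaCl was sequenced. That fraction holds DNA that is both methylated and dense in CpG.

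The series has 6 libraries, 1 for each hairpin and time. Peak lists of the 4 libraries with a Plcg1 hairpin were used. No peak list of the control libraries was used here. Per the submitters' processing notes, the tools were BWA, Picard, SAMtools and HOMER and the build was mm10, with no versions, roles or settings given there. The deposited lists hold chromosome, start and end coordinates in base pairs, with no score, count, strand or header, and starts were read as 0-based and are given here as 1-based. Each list belongs to 1 library. Whether the authors called peaks against an input or the control hairpin library, at which threshold, and whether a listed region stands for more or for less methylated DNA than in the control is not given in the sources used here. A peak below is therefore a region listed for a library and carries no direction. Read depth is unknown, so no interval or limit for methylation itself can be given. Exact binomial 95% intervals are given for shares of peaks and cover counting error only. Where a share was 0, the limit given is 3 counts of the total.

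All peaks were used as deposited. Widths were 151 bp for every peak except 1 of 120 bp in the list of hairpin 133 at 24 h. Overlap of at least 1 bp counted as shared. Chance overlap came from 1000 random placements of the second list of a pair on the same chromosomes, within the span set by the outermost peaks and genes, one-sided. On unplaced contigs only peaks set that span, so a placed peak there could fall back on a listed position and count as random overlap. The 4 lists were merged into regions by the same overlap and compared with 200 placements of all lists. Within each list, an exact McNemar test (two-sided, binomial on peaks found in only one of the other lists) compared the share found with the other hairpin at the same time with the share found at the other time with the same hairpin, with Benjamini-Hochberg adjustment. That test was added after the overlaps had been seen. Since every group is 1 library, all of these tests describe the lists and not the conditions.

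Genes came from a table of 49943 mouse RefSeq genes on GRCm38.p6, which has the coordinates of mm10, of which 21887 are protein-coding. The table has neither exons nor strand, so exon, intron, untranslated region and promoter could not be told apart. Peak centres were assigned to a protein-coding gene body, to the body of another gene only, to within 10 kb of a gene, or farther away. In place of the planned promoter class, the share of centres within 1 kb of either end of a protein-coding gene was used. Fisher's exact test (two-sided, Benjamini-Hochberg over 36 tests) compared the lists. Peaks per chromosome were set against chromosome span by exact binomial tests, two-sided, adjusted over chromosomes and lists. Peaks on unplaced contigs (2 and 1 at 0 h and 1 and 4 at 24 h, for hairpins 133 and 14) were left out of annotation and chromosome tests.

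Before the data were examined, 20 gene lists were fixed. A member counted when a peak lay in its body or within 10 kb of it, and the count was compared with 10000 random gene lists of equal size matched on window length in 10 classes, two-sided, with Benjamini-Hochberg adjustment over 140 tests (20 lists by 7 sets of peaks). The smallest p these random lists can give is 0.0002. Of the written symbols only Ahsp was not matched, and symbols that name the same gene were counted once.

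Named genes followed a rule fixed before the data were examined. It takes Plcg1 in any case, then per comparison up to 10 protein-coding genes whose body holds most of the shared regions by summed width with ties in alphabetical order, then up to 5 members of each gene list with peaks in the most lists. The rule's ranking by score and by promoter, and its widest peaks per library, were not applied because the lists have no score, the gene table has no strand and the widths are constant. Predicted genes were counted and not named. Some genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

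Some planned analyses were not run. Peak strength, a stricter subset and equal list lengths by score or width needed scores or varying widths. CpG density, CpG islands, CpG-matched placements, CpG-matched gene lists and a chromosome expectation by CpG number needed a genome sequence, which was not used here. Promoter windows and the promoter-only gene list needed strand. In place of equal lengths by score, lists were thinned at random to the shortest. Other alternatives were overlap of at least 50% of both peaks, peaks within 1 kb counted as shared, autosomes alone, neighbouring peaks within 1 kb merged, list shifts around each chromosome, peak shifts of 10 to 100 kb, removal of peaks with identical coordinates in both lists of a time, removal of chromosome 10, other annotation windows, an expectation by protein-coding genes, gene windows of 50 kb or the gene body alone, and 1 member per locus.

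The code was tested on simulated lists before use. Planted overlaps were recovered in 100% of cases with lists of 3900 peaks, and the placement test called 3% of 100 simulations without overlap. The list test over 49943 genes called 1% of random lists and 100% of lists in which every other one of 30 members held a peak. The chromosome test called some chromosome in 4% of simulations without excess and chromosome 10 in 100% when it was doubled. Smaller excesses in a gene list, families of neighbouring genes and clustered peaks were not simulated, so these rates do not cover them. Of 150 planted regions in all lists, 151 were found. The additional one was not traced, and a contig position held by all lists can give it by construction of the placements. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.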

Results

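Methylated, CpG-dense DNA was profiled in I/11 murine erythroblasts carrying 1 of 2 short hairpin RNAs against Plcg1, the gene of phospholipase C gamma 1, which acts downstream of the erythropoietin receptor. Cells were taken at 0 h and at 24 h of Epo-induced differentiation. The comparisons ask which regions were listed with both hairpins, and which stayed listed over the first day of differentiation. The 4 lists held 12963 peaks in total: 3900 with hairpin 133 and 3437 with hairpin 14 at 0 h, and 2960 and 2666 at 24 h. Peaks covered 589, 519, 447 and 403 kb. The 24 h list had 0.759 times as many peaks as the 0 h list with hairpin 133 and 0.776 times as many with hairpin 14. With 1 library per group these differences have no replicate check, and a listed region carries no direction relative to the control hairpin.

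Plcg1 itself, the targeted gene, held no peak in any list (mm10 chromosome 2, 160731310 to 160775760). The nearest peaks lay 263 kb away with hairpin 133 and 235 kb away with hairpin 14 at 0 h, and 217 kb and 2121 kb away at 24 h. A methylation library does not measure the transcript, so this does not check the knockdown.

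At 0 h, regions listed with both hairpins were most numerous in Pcdh15, a protocadherin gene of the inner ear hair cell that spans 1554 kb and held 12 shared regions among 25 peaks with hairpin 133 and 15 with hairpin 14. Lgr5, an R-spondin receptor, held 4 shared regions. Auts2, Cdh13 (T-cadherin), Cpm (carboxypeptidase M), Ntn4 (netrin 4), Prkch (protein kinase C eta) and Rtn1 held 3 each. Abr and Actb (beta-actin) held 2 each, and were the first of the genes tied at that number. Counts of regions per gene, here and below, were not adjusted for gene length. Among the genes with 3, length went from 57.9 kb (Cpm) to 1185 kb (Cdh13). Both lists had 1206 peaks in common, 30.9% of those with hairpin 133 (95% interval 29.5 to 32.4%) and 35.1% of those with hairpin 14 (33.5 to 36.7%). Random placements gave 2.74 on average and 8 at most (permutation p = 0.001, one-sided, the smallest the placements can give). The placements fall anywhere within a chromosome and are not matched on CpG density. Every pair of lists exceeded them, also pairs that share neither hairpin nor time, so this p sets no pair apart. Of the shared peaks, 958 (79.4%) had identical start and end in both lists. Lists of the same time may share a control library, and the part of the overlap that this gives was not measured.

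At 24 h, Pcdh15 again held the most regions listed with both hairpins, 8 among 13 peaks with hairpin 133 and 12 with hairpin 14. Genes with 2 shared regions included Fgf10, a fibroblast growth factor, Hmx2, a homeobox gene, Bcorl1, a corepressor gene on the X chromosome, and Cadm1, a cell adhesion gene. Arhgap27, Ccdc38, Csgalnact1 and Gpr161 also held 2. Bcorl1 had no peak at 0 h with either hairpin. The lists had 745 peaks in common, 25.2% with hairpin 133 (23.6 to 26.8%) and 27.9% with hairpin 14 (26.2 to 29.7%), against at most 7 in random placements (permutation p = 0.001, one-sided). Identical start and end were found for 691 of them (92.8%).

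Between 0 h and 24 h with hairpin 133, Pcdh15 held 9 shared regions and Lin7a, a cell polarity gene, held 3, as did Lgr5. Cpm, Arhgap9, Dhh (desert hedgehog), Efs, Fgf10 and Magi1 held 2 each, as did Pcdhga1, whose body overlaps those of other gamma protocadherins. These times had 510 peaks in common, 13.1% of the 0 h list (12.03 to 14.2%) and 17.2% of the 24 h list (15.9 to 18.6%). With hairpin 14, Pcdh15 held 8 shared regions, and Fgf10, Gjd3, Kif26b, Lhx9, Lin7a and Susd3 held 2 each. Abr and Actb held 1 each and were among the genes tied there. The times had 479 peaks in common, 13.9% of the 0 h list (12.8 to 15.1%) and 17.97% of the 24 h list (16.5 to 19.5%). Random placements gave at most 7 in each comparison of times within a hairpin (permutation p = 0.001, one-sided). Identical coordinates made up 2.75% and 2.71% of the peaks in common, and the median offset of the others was 11 and 10 bp.

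Lists that differed in both hairpin and time had about as many peaks in common as lists of the same hairpin. They had 480 peaks of hairpin 133 at 0 h in common with hairpin 14 at 24 h, and 474 peaks of hairpin 14 at 0 h with hairpin 133 at 24 h, 12.3% (11.3 to 13.4%) and 13.8% (12.7 to 14.99%) of the 0 h lists. Random placements gave at most 9 (permutation p = 0.001, one-sided). The share found at the other time was higher with the same hairpin than with the other by 0.769 and 0.145 percentage points from the 0 h lists of hairpins 133 and 14, by 1.22 from the 24 h list of hairpin 133, and was lower (-0.0750) from that of hairpin 14. None of these passed the exact McNemar test (adjusted p = 0.182, 0.941, 0.0909 and 0.957). The share found with the other hairpin at the same time exceeded that found at the other time with the same hairpin by 17.8 and 21.2 percentage points at 0 h (hairpins 133 and 14) and by 7.94 and 9.98 at 24 h (exact McNemar test, adjusted p = 5.41e-108, 1.05e-119, 2.36e-20 and 3.90e-28). Without peaks of identical coordinates, a removal that takes out most peaks shared within a time by its construction, the differences at 0 h were 3.98 and 6.01, and at 24 h they turned to -3.39 and -2.28.

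**Figure D1:**
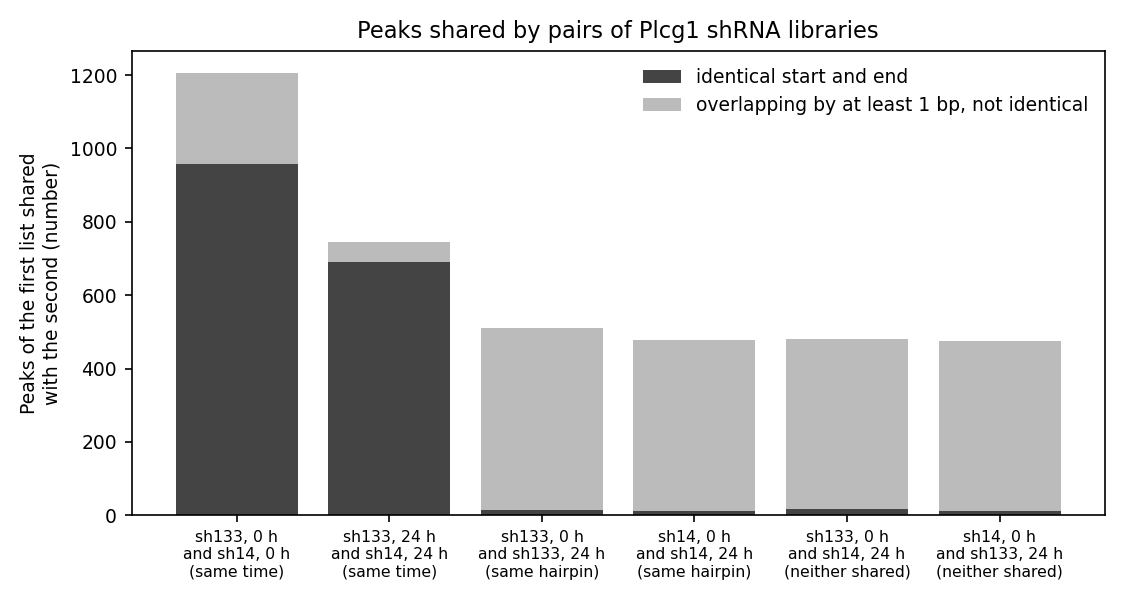
Number of peaks of the first list shared with the second for the 6 pairs of lists, split into peaks with identical start and end (dark) and other peaks overlapping by at least 1 bp (light). The 2 pairs of the same time shared 1206 and 745 peaks, of which 958 and 691 were identical, whereas the 4 pairs of different times shared 474 to 510 with 11 to 16 identical.

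In all 4 lists, Pcdh15 held 4 regions on chromosome 10, at 73821868 to 73822032, 74231733 to 74231889, 74416081 to 74416236 and 74626657 to 74626814. Fgf10 held 2 on chromosome 13, at 118715105 to 118715257 and 118715558 to 118715711, and Susd3 held 2 on the same chromosome, at 49247705 to 49247855 and 49248038 to 49248189. Adm, the gene of adrenomedullin, held 1 on chromosome 7 at 110628815 to 110628965, in a stretch that a predicted gene also covers, and Adora2a, an adenosine receptor gene, held 1 on chromosome 10 at 75317200 to 75317369. Actn1, Aldh5a1 and Arhgap27 held 1 each. The lists merged into 10085 regions, of which 7989 (79.2%) came from 1 list, 1554 from 2, 304 from 3 and 238 from all 4, against at most 1 in 200 random placements (permutation p = 0.00498, one-sided, the smallest these can give). Of 1206 regions shared by the hairpins at 0 h, the 238 were 19.7% (17.5 to 22.1%), and of 745 at 24 h they were 31.9% (28.6 to 35.4%). With peaks of identical coordinates left out, 3 regions in all lists were found.

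Peaks lay near genes more often than random placements did. The placements were not matched on CpG density, for which the assay selects. The part of this excess that comes from CpG density was not measured. Between 57.7% and 63.7% of peaks of a list were in a protein-coding gene body, against about 40.4 to 40.7% of placements. The share within 1 kb of an end of a protein-coding gene was 13.7% (12.7 to 14.8%) and 14.5% (13.3 to 15.7%) at 0 h with hairpins 133 and 14, and 19.3% (17.9 to 20.8%) and 20.9% (19.4 to 22.5%) at 24 h, against about 3.1% of placements (permutation p = 0.002, two-sided, the smallest possible). It was higher at 24 h than at 0 h with both hairpins (Fisher's exact test, adjusted p = 6.44e-09 for hairpin 133 and 1.15e-09 for hairpin 14), and the hairpins did not differ past the threshold at either time (adjusted p = 0.403 and 0.244). Regions shared by the hairpins were at gene ends in 22.2% of cases at 0 h (19.8 to 24.6%) and in 34.9% at 24 h (31.5 to 38.5%), and those in all lists in 45.1% (38.7 to 51.7%). Only 2.53% of the regions in all lists lay over 10 kb from any gene, against 34.4% of placements. Over the 36 comparisons of annotation between lists, 14 passed the adjusted threshold.

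**Figure D2:**
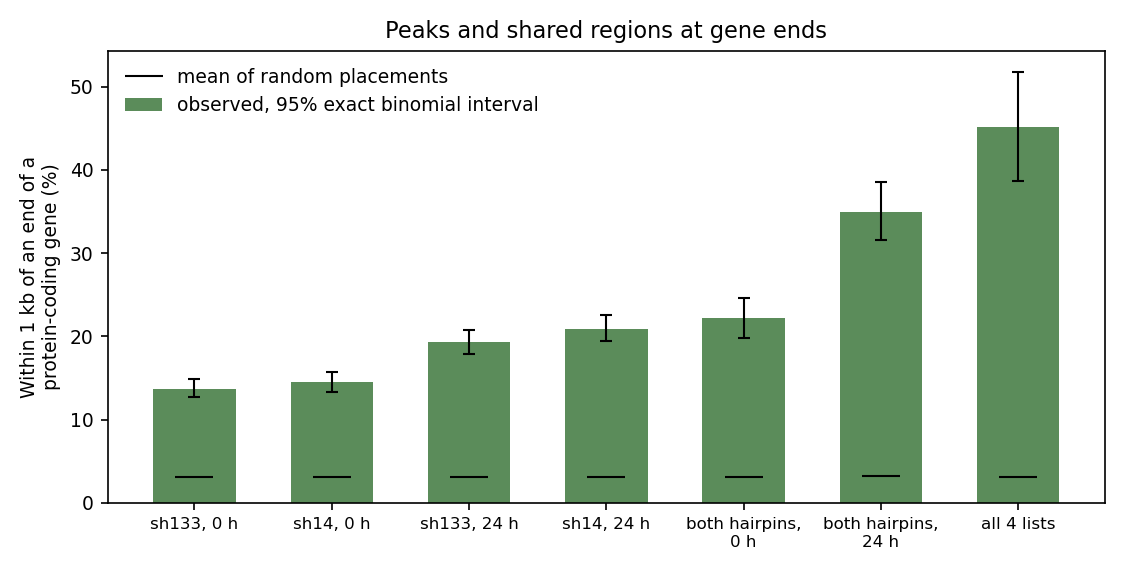
Percentage of peaks or shared regions with the centre within 1 kb of an end of a protein-coding gene, for each list, for regions shared by both hairpins at each time and for regions in all 4 lists. Bars carry exact binomial 95% intervals and dashes mark the mean of random placements, about 3.1%; the bars go from 13.7% to 45.1%.

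Chromosome 10 carried an excess of peaks in all 4 lists, 10.5% to 11.4% of peaks against 4.72% expected from its length, or 2.23 to 2.41 times as many (exact binomial test, adjusted p at most 4.93e-42). The excess lay in its distal part, where Pcdh15, Ntn4, Ccdc38, Lin7a, Lgr5 and Cpm are, and the bin from 100 to 105 Mb held 2 or 3 peaks. Chromosome 12, with Prkch and Rtn1, held 1.46 to 1.60 times the expected number (adjusted p at most 6.09e-07) and chromosome 11, with Abr and Arhgap27, 1.32 to 1.58 times (adjusted p at most 0.000381). Relative to protein-coding genes, chromosome 12 was at 2.08 to 2.29 times. Chromosome 11 was then below its expectation, at 0.808 to 0.971 times, and past the threshold in both 0 h lists (exact binomial test, adjusted p = 0.0428 and 0.00460 for hairpins 133 and 14). The X chromosome held 32 to 60 peaks, 0.182 to 0.258 times the expected number (adjusted p at most 3.13e-38). On the Y chromosome 0 peaks were listed, which allows a share of up to 0.0770% to 0.113% of a list (3 counts of its total), against 3.36% expected. The sex of the line is not among the sample details used here. How well reads can be placed on X and Y was not analysed. The low counts on X and Y therefore cannot be read as less methylated DNA.

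**Figure D3:**
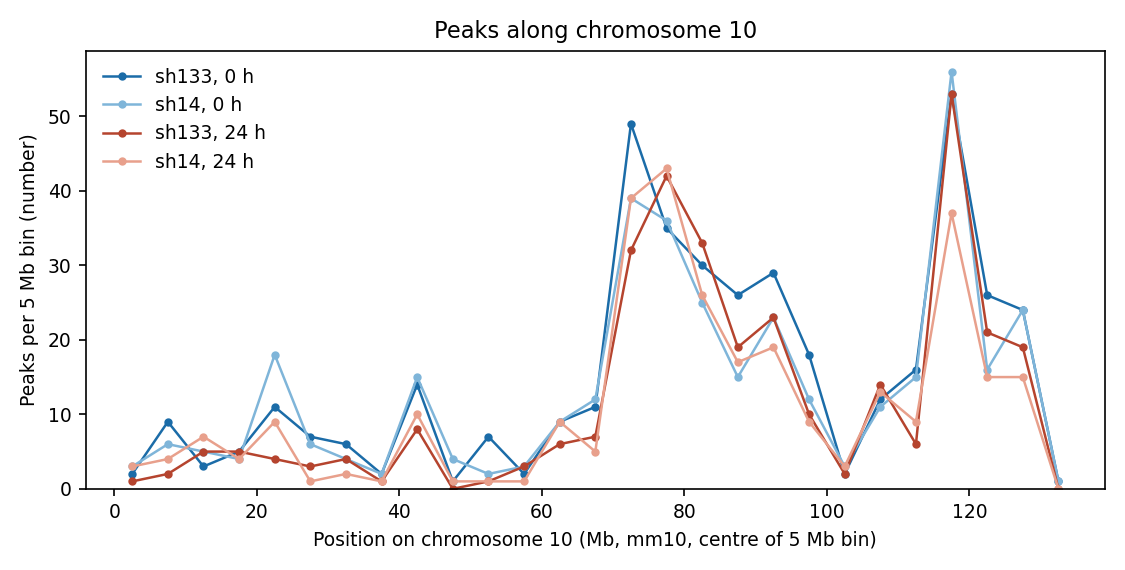
Number of peaks in each 5 Mb bin along chromosome 10 (mm10, Mb) for the 4 lists, each line one list. With hairpin 133 at 0 h, for example, the bin from 70 to 75 Mb held 49 peaks and that from 115 to 120 Mb held 53, while bins before 70 Mb held at most 14.

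Developmental transcription factor genes held peaks far more often than random genes of like length. In all gene-list tests the random genes were not matched on CpG density, for which the assay selects. The part of an excess or deficit that comes from CpG density was not measured. Among 142 homeobox, paired, T-box and Sox genes outside the Hox clusters, 52 and 46 had a peak at 0 h with hairpins 133 and 14, and 51 and 55 at 24 h, or 3.55 to 4.78 times the random mean (adjusted p = 0.00127 in each list by random lists, a permutation test). Without peaks of identical coordinates in both lists of a time, 28 and 18 had a peak at 0 h and 28 and 35 at 24 h, counts that were not tested. Regions shared by the hairpins touched 36 of them at 0 h and 32 at 24 h, and regions in all lists touched 18. All 36 and 32 were touched by regions of identical coordinates, and shared regions with an offset touched 0 of them and 0 Hox genes at either time. A control library common to both lists, if there was one, could give such identical positions. Barhl2, En1, Gsc2, Irx2 and Irx5 had peaks in every list; En1, a midbrain and hindbrain patterning gene, had 2 in each. Among 39 Hox genes, the clustered genes of body axis patterning, 20 and 21 had a peak at 0 h and 15 and 24 at 24 h (permutation test, adjusted p = 0.00127), including Hoxa10, Hoxa3, Hoxa7, Hoxa9 and Hoxc10 in every list. Neighbouring Hox genes have windows in common, and with 1 member per locus 3 and 3 of the retained Hox genes had a peak at 0 h (permutation test, adjusted p = 0.203 and 0.150 for hairpins 133 and 14) and 2 and 3 at 24 h (0.487 and 0.108). The call was then also lost in regions shared by the hairpins and in those of all lists, and with the gene body alone for hairpin 133 at 24 h (5 members, permutation test, adjusted p = 0.117) and in those of all lists (2 members, 0.226).

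Stem and progenitor regulators had peaks at 10 of 29 members with each hairpin at 24 h, counted list by list (2.48 and 2.66 times the random mean, permutation test, adjusted p = 0.0338 and 0.0187) and at 10 and 6 at 0 h with hairpins 133 and 14 (adjusted p = 0.137 and 0.814); the times were not tested against each other. Regions shared by both hairpins at 24 h touched 4 members, which was not past the threshold (permutation test, adjusted p = 0.202). Members in the most lists were Hoxa10, Hoxa7 and Hoxa9, which the Hox list also holds, then Hmga2 and Mecom. With the gene body alone the counts at 24 h were 8 and 7 (permutation test, adjusted p = 0.0784 and 0.180), and with 1 member per locus 8 and 8 (0.260 and 0.204). Lymphoid markers had a region shared by both hairpins at 0 h in 6 of 30 members (4.32 times the random mean, permutation test, adjusted p = 0.0220), and at 24 h in 1 (adjusted p = 1), a difference that was not tested. With the gene body alone 2 members were left at 0 h (permutation test, adjusted p = 1), and with 50 kb windows 7 (adjusted p = 0.179). In this list Bcl11b, a T-cell factor, had peaks in all lists, Gata3 and Zap70 in 3, and Ebf1 in 2.

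Clustered protocadherins had peaks at 20 to 23 of 57 members in each list (permutation test, adjusted p at most 0.00754), such as Pcdhga1, Pcdhga10, Pcdhga11, Pcdhga12 and Pcdhga2, but these rested on 1 to 4 distinct peaks in overlapping gene bodies. With 1 member per locus, 1 or 2 members had a peak in a list (permutation test, adjusted p at least 0.624). Olfactory and vomeronasal receptors had fewer peaks than random genes, at 4 to 10 of 1459 members in a list or 0.0949 to 0.234 times the random mean (permutation test, adjusted p = 0.00127). The members in the most lists were Olfr70, Olfr71 and Vmn1r23, then Olfr1008 and Olfr1233. Over the 140 tests, 29 passed the adjusted threshold, 22 higher and 7 lower.

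Gene groups of the erythroid programme did not pass the test in any set. Of 26 erythroid transcription factors, 5, 4, 4 and 3 had a peak (hairpins 133 and 14 at 0 h, then at 24 h), with Sox6, a factor of globin silencing, in 3 lists and Cbfa2t3, Runx1, Tcf3 and Zfpm1 in 2. Globins and haem synthesis had 2 of 25 members with a peak with hairpin 133 at 0 h, Hmox1 and Uros, and 0 in the other lists. Iron handling had likewise 2 of 16, Slc11a2 and Slc25a38, and 0 elsewhere. Red cell membrane and blood group genes had 7, 5, 7 and 4 of 27, with Dmtn in all lists, Slc14a1 and Sptbn1 in 3, and Add2 and Cd44 in 2. Epo and Kit signalling had 8, 4, 7 and 5 of 40, with Cbl in all lists and Grb2, Kit, Pik3cd and Sos1 in 2. Phospholipase C, protein kinase C and calcium signalling, the pathway of the targeted gene, had 20, 20, 18 and 11 of 68 (permutation test, adjusted p = 0.326, 0.110, 0.172 and 1), with Orai3, Plcb4, Prkch and Ryr1 in all lists and Nfatc1 in 3.

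The remaining groups also did not pass in any set. Myeloid markers had 6, 3, 4 and 3 of 28 members with a peak, led by Cebpb, Csf1r, Ly6g, Mpo and Prtn3, and megakaryocyte markers 6, 3, 3 and 2 of 20, led by Gp5, Gp1bb, Pf4, Ppbp and Vwf. Cell cycle, apoptosis and p53 pathway genes had 11, 7, 7 and 8 of 46, with Ccnd1, Cdkn2a and Rb1 in all lists and Cdk6 and Pmaip1 in 3. DNA methylation machinery had 1, 1, 3 and 3 of 30, with Mbd4 in 2 lists and Apobec1, Dnmt3a and Tet1 in 1. Germline genes had 3, 1, 4 and 3 of 46, led by Mei1, Piwil1, Tdrd5, Tdrd9 and Fkbp6. Zinc finger genes of the Zfp series had 47, 41, 33 and 31 of 394, with Zfp119b, Zfp469, Zfp672 and Zfp692 in all lists and Zfp109 in 3. Imprinted genes (5, 6, 11 and 10 of 60) and housekeeping genes (3, 3, 4 and 3 of 20) were likewise not past the threshold.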

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

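All tests in this part were chosen after the overlaps, the chromosome counts or the gene-end shares had been seen. No group has enough libraries to test for a library that stands apart.

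The hairpins shared relatively more of the 0 h lists than of the 24 h lists: the odds for a peak of hairpin 133 to be found with hairpin 14 were 1.33 times higher at 0 h (Fisher's exact test, two-sided, adjusted p = 1.58e-07). That share depends on the length of the second list: in lists thinned at random to 2666 peaks it was 23.6% at 0 h and 25.3% at 24 h, the other way round and not past the threshold (Fisher's exact test, p = 0.171). Among the shared peaks, the odds of identical start and end were 3.31 times higher at 24 h than at 0 h (Fisher's exact test, adjusted p = 3.73e-16). Both were picked out because the same comparison of hairpins differed between the times.

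Lists of the same time had more peaks in common than lists of the same hairpin. A candidate explanation is that at each time part of the positions came from a source common to both lists, such as peaks of a control library: at least 79.4% of the shared peaks of a time were identical to the base, against at most 3.33% between times. Regions called on their own in each hairpin are argued against as the whole cause, since the share of identical coordinates was at least 77.0% at 0 h and 90.6% at 24 h by the lower exact 95% bounds, against an upper bound of at most 5.36% between times; the 248 and 54 shared peaks with an offset stay open. A common effect of Plcg1 knockdown stays open and cannot be told apart from a control library used for both lists, if there was one, because the control libraries were not analysed here; 24.4% of the identical regions at 0 h recurred as identical regions at 24 h. Whether the lists of a time had a control in common is not given in the sources used here; if they had, part of their overlap may come from it, and that part was not simulated.

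Distal chromosome 10 was dense in peaks in all 4 lists. Gene density is argued against as the whole cause, since the chromosome as a whole, with no segment picked from the counts, held at least 2.30 times the peaks expected from its number of protein-coding genes in each list. A few clusters also do not account for it: without the 3 fullest bins of 1 Mb, the chromosome still had at least 1.93 times the peaks expected from its length. More copies of this segment in these cells may be a source and stay open, because read depth along the chromosome was not analysed here. At least 14 of the 26 bins of 5 Mb in each list held over 1.5 times the median of bins elsewhere with a like number of protein-coding genes. They were 11 of the 12 bins from 70 to 130 Mb, a segment picked from the counts, and 3 or 4 of the 14 before it. The bin from 65 to 70 Mb was among them (2.75 to 5 times), so that by this ratio the limits of the segment are not sharp. Its counts were 5 to 12 peaks, against 32 to 49 in the next bin. Matched medians were as low as 1 peak, and bins elsewhere were not counted against their own medians. No biological explanation was tested, since the design names none for a chromosome.

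The share of peaks at gene ends was higher at 24 h than at 0 h with both hairpins. A larger weight of recurrent regions at 24 h is argued against, since among regions of 1 list the smaller rise was still 4.73 percentage points (Fisher's exact test, p = 3.14e-07). Peaks left out of that comparison numbered 1496 of 3900 and 1446 of 3437 at 0 h (hairpins 133 and 14). At 24 h they numbered 1023 of 2960 and 1013 of 2666, a smaller part of the list with each hairpin. Peaks near Hox and the other developmental genes are also argued against as the whole cause, since they were too few to carry the rise. They numbered 91 and 83 at 0 h and 86 and 105 at 24 h (hairpins 133 and 14). Without them the smaller rise was 5.64 (Fisher's exact test, p = 5.93e-10), an outcome that their small number largely set in advance. A shorter list that holds the stronger peaks could give the same rise and stays open, because peak heights were not analysed here and the 24 h lists were shorter, down to 2666 peaks. A change over the first day of differentiation stays open too, as untested, because time, list length and any control library of that time cannot be told apart in 1 library per group.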

How the results depend on the processing

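Chosen after seeing the data were thinning to equal length, removal of identical coordinates or of chromosome 10, peak shifts of 10 to 100 kb, gene ends within 5 kb or of all genes, regions of 1 list, gene bodies alone, 1 member per locus, both chromosome alternatives (expectation by genes, merging) and, for the persistence of shared regions, all but the 50% overlap; the other alternatives were planned. Except where named here, the values that were run under alternatives (chromosomes 10, 11, 12, X and Y among the chromosomes) kept their direction and their side of the threshold or, without a test, stayed within 1.5 times the reported value. Removal of identical coordinates turned the difference between the share found at the same time and with the same hairpin at 24 h to -3.39 (hairpin 133) and -2.28 (hairpin 14) percentage points, lowered the persistence of hairpin-shared regions from 0 h to 24 h to 1.21%, and left 3 regions in all lists; this follows from its construction, since most peaks shared within a time are identical. The same removal lowered the developmental genes outside the Hox clusters with a peak to 28 and 18 at 0 h and 28 and 35 at 24 h (hairpins 133 and 14). Hox genes with a peak fell to 7 and 11 at 0 h and 3 and 14 at 24 h. These counts were not tested. Thinning left 117 regions in all lists, from fewer peaks. Keeping 1 member per locus lowered the gene-list tests past the threshold from 29 to 14, with fewer members tested; 50 kb windows gave 26 and gene bodies alone 23. Of single gene lists, 25 values were no longer past the threshold and 62 kept their side. The rise of the gene-end share was 4.73 to 6.43 points with hairpin 133 and 6.13 to 9.11 with hairpin 14 over its alternatives, and chromosome 10 stayed at 2.22 to 2.49 times its expectation. By protein-coding genes, chromosome 11 turned to below its expectation with hairpin 133 (0.862 at 0 h, 0.855 at 24 h) and hairpin 14 (0.808, 0.971). Over all chromosomes, 42 of 84 tests by length were past the threshold; by genes 16 of these kept call and direction, 2 (chromosome 11 at 0 h) were past it the other way and 24 were not past it, while 12 others were, among them chromosome 7 in all 4 lists (0.517 to 0.638 times). Taking the hairpins as 2 pairs, the mean rise of the gene-end share was 6.02 points (5.61 and 6.43), for which an exact sign-flip test cannot go below p = 0.5. Alternatives that need scores, varying widths, a genome sequence or strand were not run. Without depth or scores, a region missing from a list cannot be told from one just under the authors' threshold.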

Other observations

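The tests in this part were chosen after the overlaps had been seen, except the counts from the fixed gene lists.

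Regions shared by the hairpins fell into unlike classes. Those with identical coordinates lay at gene ends in 26.6% of cases at 0 h and 37.1% at 24 h. Those that overlapped with an offset lay at gene ends in 5.65% and 7.41% of cases (Fisher's exact test, two-sided, adjusted p = 1.25e-14 at 0 h and 2.09e-06 at 24 h). The offset class had 248 regions at 0 h and 54 at 24 h. At 0 h it touched the signalling genes Plcb4, Plcd4, Plch2, Prkca and Rasgrp1 of the phospholipase C list, Pik3cd of the Epo and Kit list and the erythroid factor gene Tcf3, each with 1 region, named here after their values were seen and with no test of these counts.

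Among imprinted genes, a list that did not pass the test in any set, Rtl1 had a peak within 10 kb in all 4 lists and Meg3, Mirg, Rian and Trappc9 in 3. The windows of Meg3, Rtl1 and Rian overlap on chromosome 12, so that 1 peak can count for more than one of them, and 0 members were in regions of all lists. Among housekeeping genes, Gapdh and Tubb5 had 1 peak within 10 kb in every list, and Actb had 2 with each hairpin at 0 h, 0 with hairpin 133 at 24 h and 1 with hairpin 14 at 24 h.

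Chromosome 10 held 8.94% of regions in 1 list (8.32 to 9.58%), 13.5% of those in 2 (11.9 to 15.3%), 14.5% in 3 (10.7 to 18.9%) and 14.7% in 4 (10.5 to 19.9%), by exact 95% intervals, of which the last 3 overlap. The X chromosome held 1.73% of regions in 1 list (1.45 to 2.04%), 1.22% in 2 (0.738 to 1.90%), 2 of 304 regions in 3 and 0 of 238 in 4, which allows up to 1.26% (3 counts of the total), too few to order. These shares were not compared by a test. Of the 238 regions in all lists, 234 held peaks of identical coordinates at both times. Regions with identical coordinates lay on chromosome 10 in 13.3% of cases at 0 h and 14.3% at 24 h. For shared regions with an offset the values were 9.27% of 248 at 0 h and 18.5% of 54 at 24 h. Recurrence over lists and identical coordinates were thus not told apart here.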
